A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

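Gene expression was measured in Saccharomyces cerevisiae with spotted arrays that read 2 channels. Per the labels, channel 1 held total RNA of a strain with benomyl and channel 2 total RNA of the same strain without it. There were 16 arrays: the wild type (WT) at 30 s and at 2, 4, 10, 20 and 40 min, and a strain deleted for YAP1 and a strain deleted for PDR1 at 30 s and at 2, 4, 10 and 20 min. Each strain and time had 1 array. Whether a column pools several hybridisations, which dye marked which channel, and whether the untreated cells were sampled at each time are not stated, so a constant dye bias of a gene cannot be separated from its response.

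The deposited values are log ratios, 1 column per array, and were taken as log2. The base is not stated; base 10 was set aside because it would make the largest ratio over a million-fold, but natural logarithms are not excluded. With natural logarithms every fold printed here would be larger, while signs, adjusted p and ranks would stay. Counts of genes at least 2-fold changed, or with an effect of at least 1 log2, could then be larger too. The ratio was read as drug-treated over untreated, from the order of the channels in the labels; with the opposite order every sign would turn. The mean of each array lay between -0.00120 and 0.00047, which shows that the authors centred each array; the method of normalisation, the background correction and any spot filter are not stated. Each array's values are thus relative to its own average, so a shift shared by all transcripts cannot be seen. No correction was added in the main analysis.

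The table held 6338 probes. A gene symbol was given for 5628 of them, none had several symbols, and 710 carried no name and are called by their number. Probes of the 17 genes with more than 1 probe were averaged, which gave 6321 features, 5611 of them named. Symbols were brought up to date through the RefSeq annotation of the yeast genome, which did not hold 5 of the named probes. No coordinates are given, because the build behind the probes is not named.

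The times shared by the 3 strains after 30 s (2, 4, 10 and 20 min) served as repeats. A linear model with a strain term and time as a block was fitted to these 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests). A strain's response is its mean log2 ratio over the 4 times, and a difference between strains is the difference of these means. Genes with a value on at least 3 of the 4 arrays of each strain were tested: 4324 features (68.4%), of which 2863 had all 12 values. A gene without missing values had 6 residual degrees of freedom, to which the shrinkage of the variances added 6.12. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and fell and rose refer to these calls. SE is the moderated standard error, with n = 4 arrays per strain. Arrays of different times are not biological replicates. The p measures a difference against the spread left after the strain and time terms, pooled over the 12 arrays. That spread holds measurement error and any strain-by-time difference, so a difference between strains that grows with time enters it. A change over time shared by the strains does not enter it. The SE of a strain's response is thus not the spread of its own 4 arrays. The time course of WT was fitted as a slope on log2 time over its 6 arrays, with at least 5 values (5248 features). A second model with strain-by-phase terms (2 and 4 min against 10 and 20 min) tested whether a difference between strains depended on time (4323 features, 4 residual degrees of freedom). Its SE and p use the spread left on all 12 arrays, also where only values at 10 and 20 min are given. If that spread is larger at 10 and 20 min than at 2 and 4 min, such SE and p are too small.

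The model was tested on simulated data with 4324 genes, 200 of them changed. For the WT response with a constant effect of 0.5 log2, 94% of the changed genes were called; for the YAP1 deletion minus WT the share was 63% at 0.5 and 98.5% at 1. With an effect of mean 1 that grew with time, 78.5% were called in the WT response and 0% in the YAP1 deletion minus WT; with mean 2 it was 0% in both. The strain-by-phase model called 99.5% for the YAP1 deletion minus WT at mean 1 when its difference at 10 and 20 min was used. With no change in any gene, the main model called 0 genes and the strain-by-phase model 1, in the WT response. False calls numbered from 0 to 17 when genes were changed. The camera test called the list that was shifted in all 3 contrasts and 0 of the other lists. In all these simulations genes were drawn independently and the effect was put into the WT arrays alone. False list calls that come from correlated genes could therefore not show, and a response shared by the strains was not simulated. Because the main model lost growing differences, the strain difference at 10 and 20 min from the strain-by-phase model was added. It was chosen after the data had been seen and is named so wherever its values stand; each strain then rests on 2 arrays, or on 1 for a gene with a missing value there.

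There were 22 gene lists, written from general knowledge of yeast: Yap1 targets of redox balance and drug export, the aryl-alcohol dehydrogenase family, Pdr1/Pdr3 targets of pleiotropic drug resistance, general stress genes of Msn2/Msn4, heat shock genes and chaperones of Hsf1, the proteasome with Rpn4, sulphur assimilation with methionine and cysteine synthesis, amino acid synthesis under Gcn4, the iron regulon of Aft1, the phosphate regulon of Pho4, ribosomal proteins, ribosome biogenesis, tubulin with the spindle and its checkpoint, tubulin folding, G1/S genes, G2/M genes, core histones, oxidative phosphorylation, ergosterol synthesis, hexose transport with glycolysis, mating type and pheromone genes, and transcription factors of the Yap1 family and of stress. Knowledge of Yap1 and Pdr1 targets may include findings from these very arrays, so those lists are not independent evidence. Each list was tested in 3 contrasts with camera at a preset correlation of 0.01, on all its tested genes. Camera at the correlation estimated from the data and fry used only members with a value on every array of the main fit. These were 4 of 10 heat shock genes, 5 of 11 G2/M genes, 7 of 18 G1/S genes, 7 of 16 transcription factors and 11 of 18 general stress genes. A gap between preset and estimated results can thus come from the genes used as well as from the correlation. That correlation is estimated from the spread left after the strain and time terms. A strain difference that grows with time and is shared by the genes of a list therefore enters it. Fry asks whether the genes of a list move on balance one way and does not compare them with other genes. For each test p was adjusted over lists and contrasts. Counts of passing members are given over all genes tested and, in those words, adjusted over the list alone.

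The genes named were fixed by a rule: for the WT response the 14 highest and 8 lowest calls with 1 sign on all 4 arrays; for the YAP1 deletion minus WT the 14 lowest and 8 highest, and for the PDR1 deletion minus WT the 12 lowest and 8 highest, by the same rule; up to 4 members of each list with the largest effect in a comparison, whether or not they passed; the 5 highest and 5 lowest slopes; the 3 highest and 3 lowest differences that depended on time; and YAP1, PDR1, PDR3, FLR1, ATR1, SNQ2, PDR5, YOR1, TRX2, GSH1, OYE3, AAD6, TUB1, TUB2 and TUB3 everywhere. Any other gene is said to have been chosen after its values were seen. The groups, lists, models, rule and most alternatives were set before the data were examined. The alternatives were array medians subtracted, arrays scaled to one spread, the 30 s array of each strain subtracted or included, no time block, other limits on missing values, robust shrinkage, arrays of the compared strains alone, an effect of at least 1 log2, linear time, and arrays or times left out in turn. Added later were the values at 10 and 20 min, a running median over 25 probe numbers subtracted from each array, the model without the 3 arrays (1 per strain) with the strongest trend along probe numbers from 2 min on, and arrays left out in turn from the strain-by-phase model. The main model left out the 30 s arrays and the 40 min WT array; both WT arrays entered the time trend. The deletions have no 40 min array.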

Results

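The arrays followed the first 40 min after addition of benomyl, a drug that depolymerises microtubules, in WT yeast and in strains that lack the transcription factor Yap1, which activates genes of the oxidative stress and drug response, or Pdr1, which activates drug efflux pumps. WT gave 6 arrays and each deletion strain 5, with 1 array per strain and time. Between 3450 and 6128 of the 6338 probes had a value on an array; the lowest number was that of the PDR1 deletion at 2 min. The number of arrays limits the precision, and the spot intensities were not used here. All values are log2 ratios of drug-treated over untreated cells of the same strain, if base and direction are read correctly; positive values mean more transcript with the drug, relative to the average of the array.

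The number of genes 2-fold up grew with time in WT. There, 1 gene was at least 2-fold up at 30 s, 9 at 2 min, 25 at 4 min, 72 at 10 min, 159 at 20 min and 246 at 40 min. Genes at least 2-fold down in WT numbered 8 at 30 s, 12 at 2 min, 1 at 4 min, 3 at 10 min, 101 at 20 min and 206 at 40 min. At 20 min the YAP1 deletion had 30 genes up and 32 down, and the PDR1 deletion 70 up and 40 down. The standard deviation of an array ranged from 0.17 to 0.59. These are counts on single arrays with no test.

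**Figure D1:**
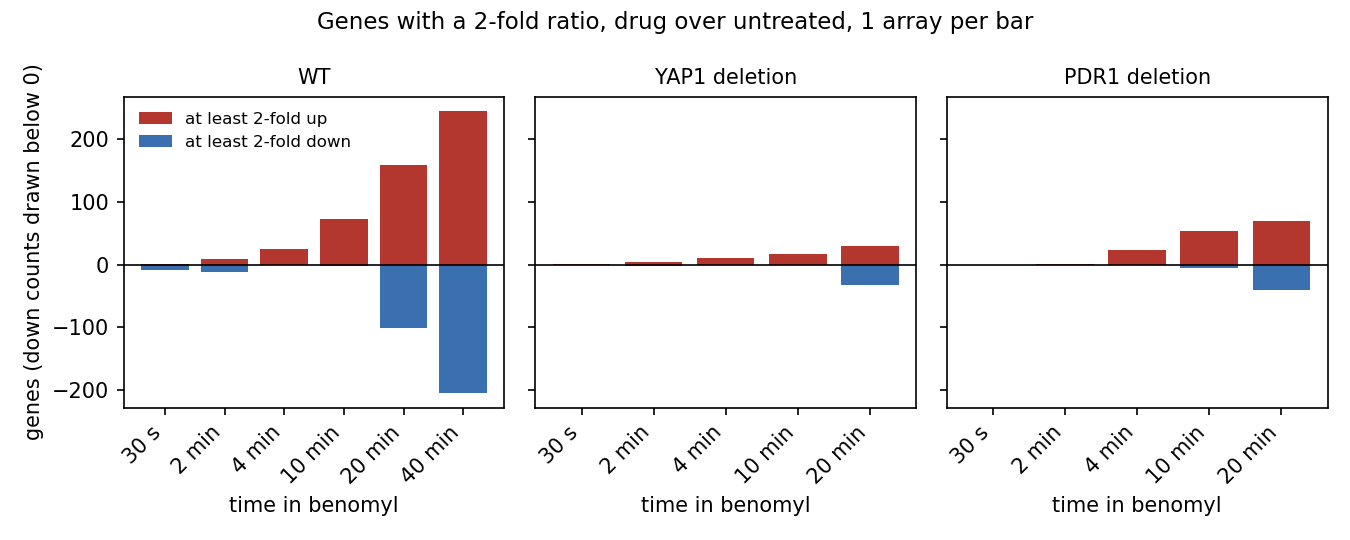
Number of genes with a ratio of at least 2-fold on each array, by strain and time in benomyl, up above 0 and down below 0. WT reached 246 genes up and 206 down at 40 min, and the YAP1 deletion 30 up and 32 down at 20 min.

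The first comparison asked which transcripts benomyl changed in WT. FLR1, an exporter of the major facilitator family that gives benomyl resistance, rose most and averaged 3.65 ± 0.47 (SE, n = 4 arrays; adjusted p = 0.00137), which is 12.6-fold. FLR1 stood at 0.06 at 30 s, 0.82 at 2 min, 5.48 at 10 min and 3.81 at 40 min. The next highest were YML131W (3.59 ± 0.37), FRM2 (3.58 ± 0.60), YCR102C (3.47 ± 0.41) and the methylglyoxal reductase GRE2 (3.17 ± 0.38). The glutathione transferase ECM4 rose by 2.51 ± 0.43. BTN2, a chaperone that sorts misfolded proteins, rose by 2.46 ± 0.34. Among the strongest decreases were AMN1 (-0.77 ± 0.13), which acts in daughter cell separation and mitotic exit, RNR1 (-0.69 ± 0.12), the large subunit of ribonucleotide reductase, the iron oxidase FET3 (-0.54 ± 0.09) and FAR1 (-0.54 ± 0.12), which inhibits the G1 cyclin kinase.

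In all, 180 of 4324 genes passed in the WT response, 113 up and 67 down, and 33 of those up but 0 of those down averaged 2-fold or more (limma; 854 genes at an unadjusted p under 0.05, where chance gives 216). The other genes of the rule that rose were CIS1 (2.55), YLR460C (2.55), the membrane protein SNG1 (2.27, smallest adjusted p = 8.08e-05), AAD14 (2.10), OSI1 (2.08), the exporter ATR1 (1.94) and the isomaltase IMA4 (1.87). INA1 (-0.60), UTR2 (-0.53), NOG2 (-0.51) and the unnamed probe_5179 (-0.51) fell. The ABC transporters SNQ2 (1.55 ± 0.20) and PDR5 (1.06 ± 0.20) rose, as did AAD6 (1.62), GSH1 (0.87), which starts glutathione synthesis, and the thioredoxin TRX2 (0.76). The transporter YOR1 (0.42, adjusted p = 0.111) and OYE3 (0.76, adjusted p = 0.0957) did not pass. YAP1 itself averaged 0.02, and the tubulin genes TUB1 (-0.03), TUB2 (0.12) and TUB3 (-0.01), whose products are the target of the drug, did not pass. PDR1 and PDR3 had too few values to be tested.

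The WT count depends on the model and leans on the later arrays. With the WT arrays alone limma called 0 genes (457 at an unadjusted p under 0.05), and without the time block 48 passed. Otherwise 34 genes passed without the 10 min arrays, 55 without the 20 min arrays, and 101, 105, 60 and 37 without the WT array at 2, 4, 10 and 20 min. Without the array of each strain, from 2 min on, whose ratios most follow the order of the probes (WT and the YAP1 deletion at 4 min, the PDR1 deletion at 2 min), 12 genes passed, and the split of calls into up and down moved from 113 and 67 to 141 and 41 with array medians subtracted and to 110 and 16 with scaled arrays.

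Of the Yap1 targets, 16 of 22 tested rose and 0 fell, with a mean of 1.35 and FLR1, YML131W, FRM2 and ECM4 highest; 19 passed when adjusted over the list alone. The list stood out from other genes in camera (adjusted p = 2.32e-24), but not with its own correlation (adjusted p = 0.168 with an estimated correlation). All 22 tested members were used there. The estimated correlation of 0.541 also holds any strain difference that grew with time and was shared by the list. Of the aryl-alcohol dehydrogenases, which reduce aldehydes and share much of their sequence, AAD14, AAD6 and AAD3 (0.67) rose and 2 of 5, AAD4 (0.72) among them, did not pass. Adjusted over the list alone 4 rose, and the list mean of 1.04 gave adjusted p = 5.79e-06, or adjusted p = 0.276 with an estimated correlation. Of the Pdr1/Pdr3 targets, 7 of 14 rose, led by GRE2, CIS1, SNQ2 and PDR5, and 11 rose adjusted over the list alone. Their mean was 0.88 (camera, adjusted p = 1.11e-12, or adjusted p = 0.156 with an estimated correlation). GRE2, CIS1 and SNQ2 also rose in the PDR1 deletion, while PDR5, TPO1, TPO4 and ICT1 did not pass there. The rise of this list therefore cannot be read as a response through Pdr1 alone. At 40 min PDR5 stood at -0.48 and this list at a mean of 0.12, down from 1.33 at 10 min, while the Yap1 list stood at 2.13 at 10 min and 1.62 at 40 min. These means run over the members with a value on each array, which can differ between times.

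Of the heat shock genes and chaperones, 6 of 10 rose, 8 adjusted over the list alone, among them BTN2, HSP42 (1.16), STI1 (0.97) and MDJ1 (0.95). The list mean of 0.84 gave adjusted p = 4.37e-10, or adjusted p = 0.156 with an estimated correlation; 11 of the 21 genes listed were not tested, as many had no value in the PDR1 deletion. Of the general stress genes 3 of 18 rose, RTN2 (1.27) and SPI1 (0.98) among them, while TSL1 (0.87) and HSP12 (0.61) did not pass. Adjusted over the list alone 3 rose and 1 fell (mean 0.27; adjusted p = 0.00159; adjusted p = 0.409 with an estimated correlation). Of the sulphur genes 5 of 17 rose, 8 adjusted over the list alone, such as MET17 (0.67) and the methionine permease MUP1 (0.61), against MET16 (0.66) and MET14 (0.57), which did not pass. The list mean was 0.27 (adjusted p = 1.50e-06; adjusted p = 0.156 with an estimated correlation). Of the amino acid synthesis genes 4 of 22 rose, LYS21 (0.76), LYS20 (0.53), ILV2 (0.42) and LEU4 (0.36), and 7 rose and 1 fell adjusted over the list alone. Their mean was 0.16 (adjusted p = 0.000128; adjusted p = 0.326 with an estimated correlation). In hexose transport and glycolysis 1 of 14 rose, the transporter HXT2 (0.46), 3 adjusted over the list alone, with a mean of 0.16 (adjusted p = 0.00022; adjusted p = 0.156 with an estimated correlation). The proteasome list had 0 of 28 members past limma's threshold and 0 adjusted over the list alone; its mean was 0.05 (adjusted p = 0.0353; adjusted p = 0.63 with an estimated correlation), with its regulator RPN4 at 0.33.

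Of the core histones 5 of 7 fell, 6 adjusted over the list alone, with HTA1 (-0.39), HHF1 (-0.36), HTB2 (-0.35) and HTA2 (-0.34) lowest and a list mean of -0.32 (adjusted p = 1.54e-05; adjusted p = 0.276 with an estimated correlation). Of the G1/S genes 1 of 18 fell, RNR1, and 3 adjusted over the list alone; MNN1 (-0.56), POL1 (-0.45) and CLN2 (-0.43) did not pass. The mean was -0.22 (adjusted p = 0.00102; adjusted p = 0.333 with an estimated correlation). Of the G2/M genes 1 of 11 fell, the replication helicase subunit MCM7 (-0.43), and 2 adjusted over the list alone (mean -0.19; adjusted p = 0.0123; adjusted p = 0.703 with an estimated correlation). In ribosome biogenesis 2 of 45 fell, NOG2 and NSA2 (-0.40), also 2 adjusted over the list alone, with a mean of -0.15 (adjusted p = 0.000172; adjusted p = 0.409 with an estimated correlation). The ribosomal proteins had 0 of 87 members past limma's threshold and 0 adjusted over the list alone, with a mean of -0.08 (adjusted p = 0.0280; adjusted p = 0.791 with an estimated correlation) and RPS25A at -0.30. Of the mating genes 2 of 14 fell, FAR1 and the receptor STE3 (-0.34), and 6 adjusted over the list alone (mean -0.17; adjusted p = 0.0219; adjusted p = 0.342 with an estimated correlation). Of the phosphate regulon 2 of 9 fell, PHO11 (-0.33) and PHM6 (-0.34), and 4 adjusted over the list alone (mean -0.15; adjusted p = 0.0478; adjusted p = 0.326 with an estimated correlation).

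Other lists were not called in the WT response. The iron regulon had 1 of 14 members up, ISU2 (0.60), and 1 down, FET3, the same numbers adjusted over the list alone (adjusted p = 0.345). Tubulin, spindle and checkpoint genes had 0 of 16 past limma's threshold and 3 down adjusted over the list alone (mean -0.11; adjusted p = 0.0858). Tubulin folding (13 tested, adjusted p = 0.581) and oxidative phosphorylation (24 tested, adjusted p = 0.391) had 0 members past either threshold. Ergosterol synthesis (19 tested, adjusted p = 0.0988) had 2 down adjusted over the list alone, with ERG3 at -0.53. Of the transcription factors 1 of 16 rose, YRR1 (0.86), a regulator of drug resistance genes, and adjusted over the list alone 3 rose and 2 fell (adjusted p = 0.364). Across all contrasts no list call held with an estimated correlation. That test and fry used only members with a value on every array of the main fit, such as 4 of 10 heat shock genes. The general stress (adjusted p = 0.626), proteasome (adjusted p = 0.349), phosphate (adjusted p = 0.583), ribosome biogenesis (adjusted p = 0.107), G2/M (adjusted p = 0.418) and mating (adjusted p = 0.626) calls were also lost with the 30 s array subtracted, and those of the phosphate regulon (adjusted p = 0.126) and the ribosomal proteins (adjusted p = 0.689) without the 3 arrays that follow probe order. With the trend along probe numbers removed, those of the proteasome (adjusted p = 0.0644), the phosphate regulon (adjusted p = 0.0627) and the ribosomal proteins (adjusted p = 0.128) were lost. With fry, which asks only whether a list's own genes move one way, 10 of the lists called in WT passed: Pdr1/Pdr3, heat shock and sulphur (adjusted p = 0.0105), core histones and phosphate (adjusted p = 0.0139), Yap1 (adjusted p = 0.0169), hexose transport and glycolysis (adjusted p = 0.0234), mating (adjusted p = 0.0277), G1/S (adjusted p = 0.0289) and the aryl-alcohol dehydrogenases (adjusted p = 0.0451). Amino acid synthesis (adjusted p = 0.0668), ribosome biogenesis (adjusted p = 0.0860), G2/M (adjusted p = 0.177), general stress (adjusted p = 0.185), ribosomal proteins (adjusted p = 0.328) and the proteasome (adjusted p = 0.519) did not pass it.

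**Figure D2:**
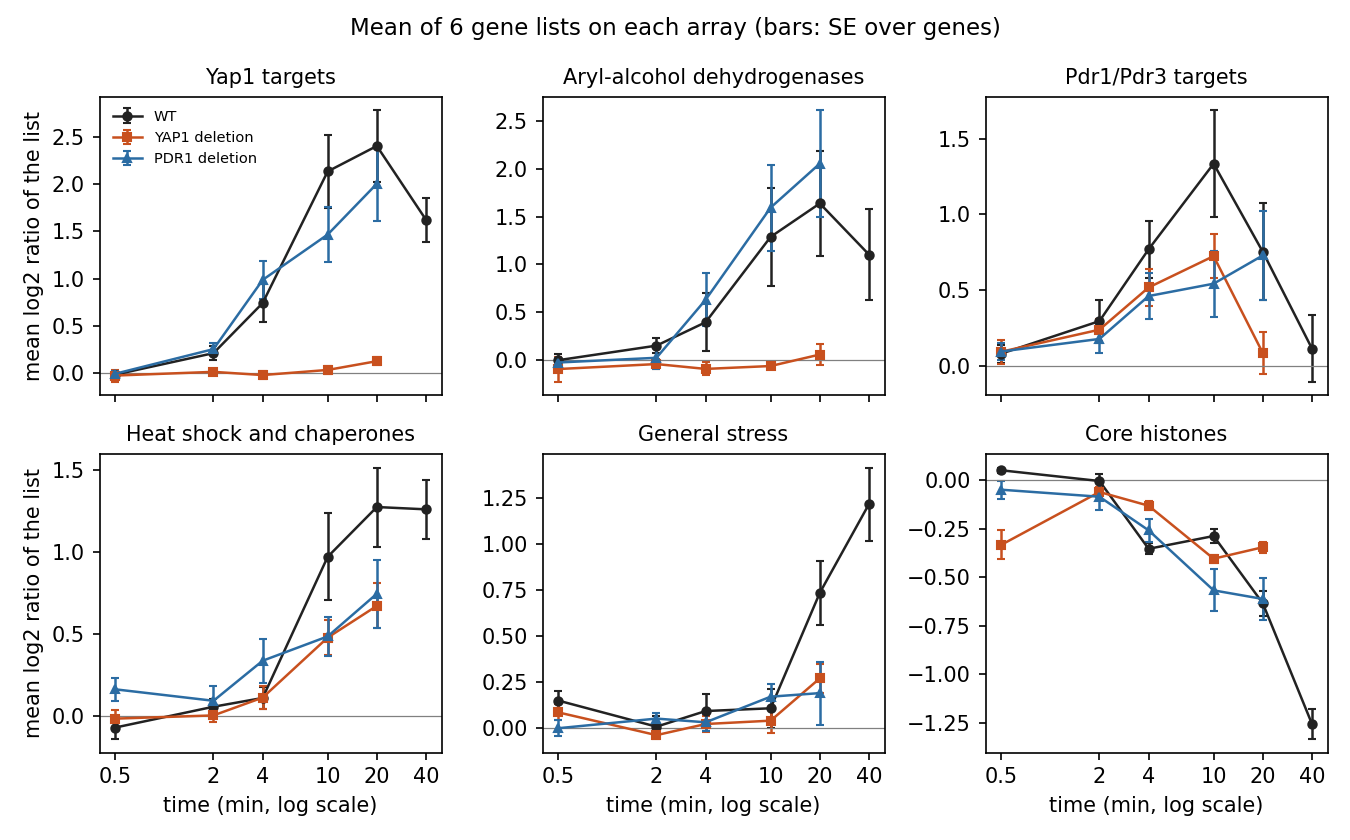
Mean log2 ratio of 6 gene lists on each array against time on a log scale, by strain, with bars for the SE over genes and not over arrays. Each mean runs over the members with a value on that array. The Yap1 list reached 2.40 in WT and 2.00 in the PDR1 deletion at 20 min, and 0.13 in the YAP1 deletion.

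The slope over the WT time course asked which transcripts changed steadily from 30 s to 40 min. The chaperone SSA2 rose by 0.34 ± 0.04 log2 per doubling of time (n = 6 arrays), its co-chaperone STI1 by 0.29 ± 0.04 and the fumarate reductase FRD1 by 0.34 ± 0.04; the unnamed probe_4689 rose by 0.37 and probe_4825 fell by 0.32. In limma these were the 5 calls among 5248 genes, with adjusted p from 0.0318 to 0.0426 (1087 at an unadjusted p under 0.05, 262 by chance). No gene passed when the array at 2, 4 or 20 min was left out, and 59 or 16 passed without the one at 30 s or 40 min. On linear minutes 662 genes passed.

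The next comparison asked what remains of the response without Yap1. In the YAP1 deletion VHR1, a regulator of biotin genes, rose by 1.13 ± 0.11 and ICT1, a lipid acyltransferase and Pdr1 target, by 1.03 ± 0.13. HXT2 (0.56 ± 0.09), the glutamate dehydrogenase GDH3 (0.51 ± 0.08) and STB2 (0.42 ± 0.07) rose as well. VHR1, GDH3 and STB2 were chosen after their values were seen. FLR1 averaged -0.02 and ATR1 -0.19, and the largest FLR1 value of the 5 arrays was 0.13. PDR5 averaged 0.80 (adjusted p = 0.276) and stood at 0.64 at 4 min, 2.24 at 10 min and 0.00 at 20 min. These 5 genes were the calls in limma, all up and all also up in WT, where independent lists would share 0.131 (416 genes at an unadjusted p under 0.05). Both lists come from the same fit with a shared spread per gene, and a constant dye bias would repeat in each strain. Independent lists are therefore not a fair measure of chance here. At 10 and 20 min, in a model added after the data had been seen, 8 genes passed, 6 up and 2 down: BTN2 (1.97 ± 0.12), ICT1 (1.22), SNG1 (1.13), HSP42 (1.13) and MDJ1 (0.78) rose and INA1 (-0.68) fell. That is 3 of 10 heat shock genes up, against 0 over 2 to 20 min. The count of 8 was 2 without the WT array at 2 min, 1 without the strain's own array at 10 min, 3 without any other of its arrays and 17 without the WT array at 10 min or with scaled arrays. Among the Yap1 targets 0 of 22 passed and the mean was 0.02. The count was 2, 0 and 1 without the 2, 4 or 10 min arrays, 1 without the strain's own array at 2 min, 0 without its array at 4 or 10 min, 2 without the WT array at 2, 4 or 10 min or the PDR1 deletion array at 2 or 10 min, 3 without the WT array at 20 min, 24 with scaled arrays, 1 with the strain's own arrays alone, 1 without the time block and 12 with the 30 s arrays included.

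Measured directly, the difference between the YAP1 deletion and WT was led by Yap1 targets. YML131W was lower in the deletion by a log2 difference of -3.50 ± 0.52 (SE, n = 4 arrays per strain), ATR1 by -2.13 ± 0.32 and the NADPH oxidoreductase OYE2 by -1.75 ± 0.24. SNG1 (-1.61 ± 0.25), CCS1 (-1.36 ± 0.22), the copper chaperone of superoxide dismutase, and AFG1 (-1.35 ± 0.21), a mitochondrial ATPase, followed. Each of the 6 was lower in the deletion at all 4 times. In limma these were the calls among 4324 genes, at adjusted p = 0.0401 for CCS1 and adjusted p = 0.0257 for the others (373 genes at an unadjusted p under 0.05, 216 by chance). FLR1 differed by -3.67 ± 0.67 and missed the threshold (adjusted p = 0.0598). GSH1 (-0.88, adjusted p = 0.0852), AAD6 (-1.63, adjusted p = 0.191), SNQ2 (-0.87), TRX2 (-0.68) and OYE3 (-0.56) did not pass, nor did PDR5 (-0.26), YOR1 (0.02) and the tubulin genes.

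The count of 6 is fragile. It was 0 without the 4, 10 or 20 min arrays, without the YAP1 deletion array at 4, 10 or 20 min, the WT array at 10 or 20 min, the PDR1 deletion array at 4 or 10 min, or the 3 arrays that follow probe order, 2 without the WT array at 4 min or the PDR1 deletion array at 20 min, and 24, 16 and 27 without the 2 min arrays, the WT one alone or the YAP1 deletion one alone. With only the arrays of these 2 strains limma called 0 genes (466 at an unadjusted p under 0.05) and without the time block 0; robust shrinkage left 2 and the 30 s arrays included left 1.

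At 10 and 20 min, in the model chosen after the data had been seen, the difference was wide. FRM2 differed by -6.36 ± 0.53, FLR1 by -5.37 ± 0.50 (adjusted p = 0.000119), YCR102C by -5.20 ± 0.38, YML131W by -4.92 ± 0.41, GRE2 by -4.55 ± 0.40 and ECM4 by -4.43 ± 0.26 (2 arrays per strain). Of 4323 genes 64 passed, 55 lower and 9 higher in the deletion, and all 55 were among the 194 that rose in WT at these times, a number that was 60 without the WT array at 20 min, 132 without the one at 10 min and 97 with scaled arrays. The same WT arrays enter both lists, which favours this overlap, and it was not tested. AMN1 was higher in the deletion (1.13 ± 0.21). The count was 31 without the YAP1 deletion array at 20 min, 41 without the WT array at 20 min and 38 with scaled arrays. The SE and p of this model also draw on the spread left at 2 and 4 min. The standard deviation of the WT arrays was 0.24 and 0.27 there, against 0.40 and 0.54 at 10 and 20 min. In the YAP1 deletion it was 0.17 and 0.23 against 0.24 and 0.30. These values hold the response too, so whether the SE are too small was not tested.

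Of the Yap1 targets 3 of 22 were lower in the YAP1 deletion over 2 to 20 min, YML131W, ATR1 and OYE2, 16 adjusted over the list alone and 17 at 10 and 20 min. FRM2 (-3.69), FLR1 and ECM4 (-2.40) did not pass over 2 to 20 min. The list mean was -1.33 (adjusted p = 2.32e-24; adjusted p = 0.168 with an estimated correlation; fry adjusted p = 0.0598). Of the aryl-alcohol dehydrogenases 0 of 5 passed in limma, 4 adjusted over the list alone and 4 at 10 and 20 min (mean -1.10; adjusted p = 1.50e-06; adjusted p = 0.243 with an estimated correlation). Of the Pdr1/Pdr3 targets 0 of 14 passed and 3 adjusted over the list alone; GRE2 (-2.92, adjusted p = 0.061) and CIS1 (-1.82, adjusted p = 0.149) did not pass over 2 to 20 min but were lower at 10 and 20 min, by -4.55 and -2.91. The mean of that list was -0.42, its median -0.08 (adjusted p = 0.0378; adjusted p = 0.333 with an estimated correlation), and the call was lost with array medians subtracted (adjusted p = 0.0611), with the 30 s array subtracted (adjusted p = 0.0999) and with the trend along probe numbers removed (adjusted p = 0.0557).

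Smaller list shifts in the same contrast had 0 members past limma's threshold over 2 to 20 min. At 10 and 20 min, in the added model, 4 of 10 heat shock genes were lower, BTN2 (-2.39), HSP104 (-1.73), HSP42 (-1.60) and MDJ1 (-1.31), 3 of them on 1 WT array, since HSP104 had no WT value at 20 min and HSP42 and MDJ1 none at 10 min. Also lower were TSL1 (-2.50) of general stress (no WT value at 10 min) and LYS21 (-1.07) of amino acid synthesis. The heat shock list had a mean of -0.39 with BTN2 at -1.24 (1 down adjusted over the list alone; adjusted p = 0.00088; adjusted p = 0.333 with an estimated correlation). General stress stood at -0.21 with TSL1 at -0.93 (1 down adjusted over the list alone; adjusted p = 0.0202; adjusted p = 0.63 with an estimated correlation). The sulphur list stood at -0.15 (0 adjusted over the list alone; adjusted p = 0.00701; adjusted p = 0.243 with an estimated correlation) and the proteasome at -0.09 (0 adjusted over the list alone; adjusted p = 0.00386; adjusted p = 0.51 with an estimated correlation). Amino acid synthesis stood at -0.12 with LYS21 at -0.72 (1 down adjusted over the list alone; adjusted p = 0.0072; adjusted p = 0.342 with an estimated correlation), and the mating genes at 0.13 with FIG1 at 0.49 (1 up adjusted over the list alone; adjusted p = 0.0453; adjusted p = 0.342 with an estimated correlation). The mean of the mating list turned to -0.03 with the 30 s arrays subtracted, a setting that also ended the calls of general stress (adjusted p = 0.399), the proteasome (adjusted p = 0.468), sulphur (adjusted p = 0.0714) and amino acid synthesis (adjusted p = 0.626). The mating call was also lost with the trend along probe numbers removed (adjusted p = 0.0885). The other 13 lists were not called (adjusted p from 0.118 to 0.944); at 10 and 20 min MNN1 (0.94) of the G1/S genes was higher and YRR1 (-1.71) of the transcription factors lower. With fry no list passed in this contrast (adjusted p from 0.0598 to 0.928). Mean, median and test differed in sign for the iron regulon (mean 0.03, median -0.03, camera down), tubulin folding (mean -0.01, median 0.01), glycolysis (mean 0.02, median -0.0015) and the transcription factors (mean -0.01, median 0.01, camera up).

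**Figure D3:**
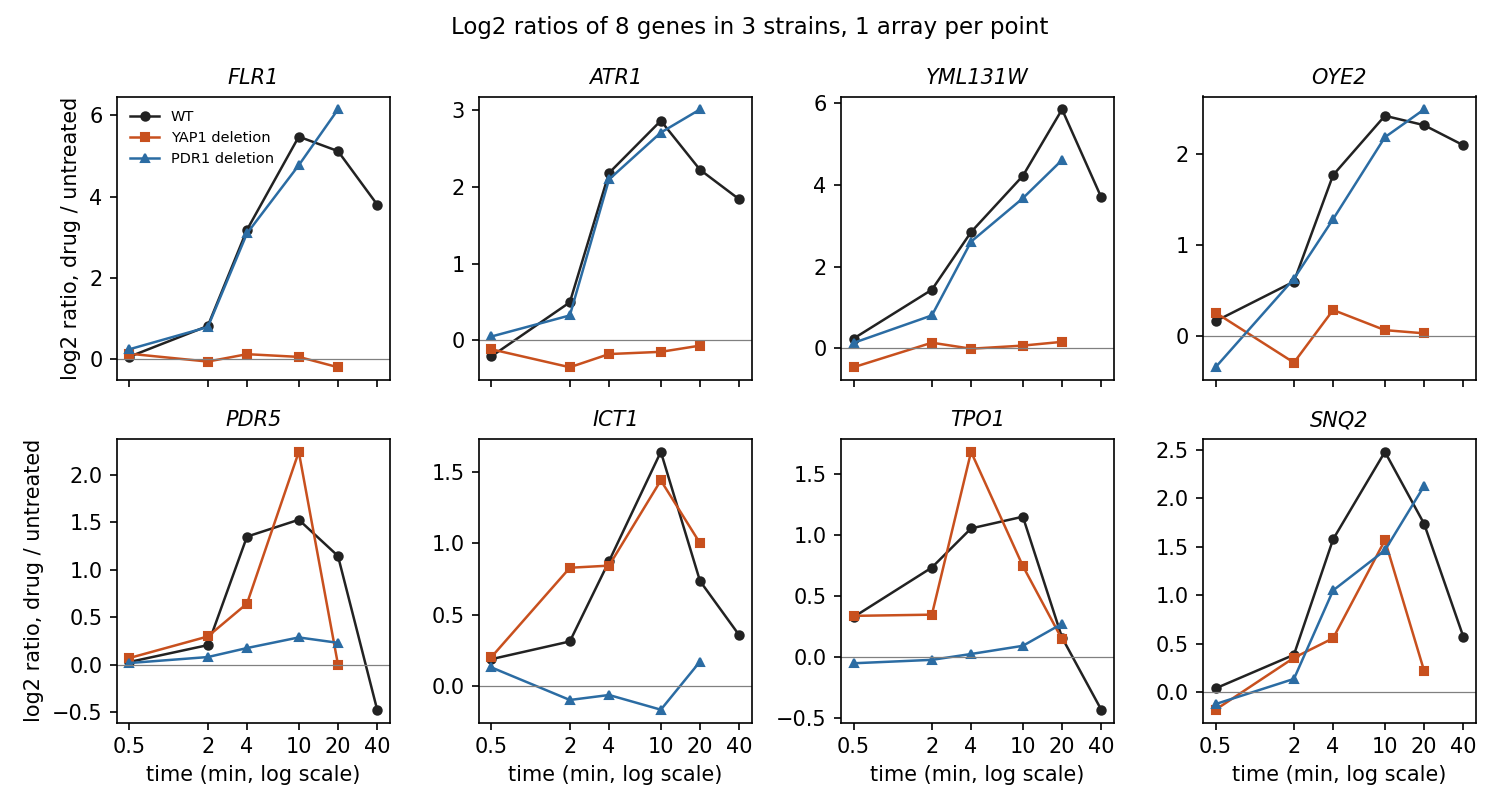
Log2 ratio of 8 genes against time on a log scale, 1 point per array, in WT and the YAP1 and PDR1 deletions. FLR1 reached 5.48 in WT and 6.15 in the PDR1 deletion and no more than 0.13 in the YAP1 deletion, while PDR5 stood at 0.29 or less on every array of the PDR1 deletion.

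Without Pdr1, 15 of 22 Yap1 targets rose. In the PDR1 deletion FLR1 rose by 3.70 ± 0.47, ATR1 by 2.04 ± 0.22, OYE3 by 1.63 ± 0.24, AAD6 by 1.51 ± 0.29 and SNQ2 by 1.19 ± 0.20. PDR5 averaged 0.19 (adjusted p = 0.594) and stood between 0.17 and 0.29 at 4, 10 and 20 min. In limma 238 of 4324 genes passed, 121 up and 117 down (1029 at an unadjusted p under 0.05). Of the calls 59 up and 19 down were shared with WT, where independent lists would share 3.16 and 1.81. The shared fit and any constant dye bias favour this overlap as well, and it was not tested. Of the Pdr1/Pdr3 targets 5 of 14 rose, namely SNQ2, YOR1 (0.56), GRE2, CIS1 and IPT1. GRE2 and CIS1, the highest of this list in WT, thus rose without Pdr1 too. Of the aryl-alcohol dehydrogenases 3 of 5 rose. Of the core histones 4 of 7 fell. Without the 4, 10 or 20 min arrays 77, 36 and 60 genes passed, without the strain's own array at 2, 4, 10 or 20 min 102, 153, 56 and 90, without the YAP1 deletion array at 4 min 149, and without the 3 arrays that follow probe order 67; scaled arrays gave 132. With the strain's own arrays alone 4 genes passed, and without the time block 130.

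Between the PDR1 deletion and WT no gene passed. The arrays of this strain held 0 values of exactly 0, against 3 to 17 on every other array, so their processing may differ, and strain and processing cannot be separated. PDR5, the main multidrug pump, differed by -0.86 ± 0.29 (adjusted p = 0.235), ICT1 by -0.93 ± 0.18 (adjusted p = 0.122), CIS1 by -0.95 ± 0.43 (adjusted p = 0.340) and the polyamine exporter TPO1 by -0.68 ± 0.23 (adjusted p = 0.235). FLR1 (0.05 ± 0.67), ATR1 (0.09), SNQ2 (-0.35), YOR1 (0.14), TRX2 (-0.13), GSH1 (-0.20) and AAD6 (-0.12) differed by less than 0.5, and OYE3 was 0.87 ± 0.33 (adjusted p = 0.290). Limma called 0 of 4324 genes, with a smallest adjusted p = 0.0994 and 617 genes at an unadjusted p under 0.05 (216 by chance). The 30 s arrays subtracted gave 388 calls, in a setting where the same 30 s values enter all arrays of a strain.

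At 10 and 20 min, in the added model, 12 genes passed, 7 lower and 5 higher in the PDR1 deletion. The lower ones included BTN2 (-2.78 ± 0.17), the metallothionein CUP1-1 (-2.89 ± 0.29), the disaggregase HSP104 (-2.24 ± 0.26), the trehalose synthesis subunit TSL1 (-2.69 ± 0.28), ECM4 (-2.39 ± 0.26) and the aldolase FBA1 (-1.43 ± 0.16); MNN1 was higher (1.18 ± 0.16). In WT, HSP104 had no value at 20 min and CUP1-1 and TSL1 none at 10 min, so their WT value rests on 1 array. The count was 3 without the WT array at 20 min, 2 without the PDR1 deletion array at 20 min, 50 and 45 without the 10 min array of WT or of the deletion, and 4 with scaled arrays.

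Of the Pdr1/Pdr3 targets 0 of 14 passed in this difference and 1 was lower adjusted over the list alone; the mean was -0.42 (adjusted p = 0.000172; adjusted p = 0.333 with an estimated correlation). Of the genes of hexose transport and glycolysis 0 of 14 passed and 5 were lower adjusted over the list alone, with FBA1 at -0.70, GPM1 at -0.55, the pyruvate kinase CDC19 at -0.47 and TDH2 at -0.45. Their mean was -0.25 (adjusted p = 0.000157; adjusted p = 0.156 with an estimated correlation; fry adjusted p = 0.0139). The ribosomal proteins had 0 of 87 past either threshold and a mean of -0.13 (adjusted p = 3.36e-07; adjusted p = 0.483 with an estimated correlation). The heat shock list had 0 of 10 past either threshold, with BTN2 at -1.19 and a mean of -0.34 (adjusted p = 0.0207; adjusted p = 0.342 with an estimated correlation). The G2/M list had 0 of 11 past limma's threshold and 1 higher adjusted over the list alone, with MCM7 at 0.63 and a mean of 0.23 (adjusted p = 0.00986; adjusted p = 0.537 with an estimated correlation). The Yap1 targets were not called (mean -0.16; adjusted p = 0.0988), with ECM4 at -1.20. The remaining 16 lists were not called (adjusted p from 0.0858 to 0.944). Mean and median differed in sign for the aryl-alcohol dehydrogenases (mean 0.04, median -0.12), tubulin folding (mean -0.01, median 0.01) and the transcription factors (mean -0.00055, median 0.00088). With the 30 s arrays subtracted the calls of the heat shock list (adjusted p = 0.0725), the ribosomal proteins (adjusted p = 0.224) and the G2/M list (adjusted p = 0.628) were lost. With fry the Pdr1/Pdr3 list (adjusted p = 0.150), the heat shock list (adjusted p = 0.177), the G2/M list (adjusted p = 0.185) and the ribosomal proteins (adjusted p = 0.212) did not pass. At 10 and 20 min 2 of 10 heat shock genes, BTN2 and HSP104, were lower, as were TSL1, FBA1 and ECM4, 1 each in their lists, and SIT1 of the iron regulon and MNN1 were higher.

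**Figure D4:**
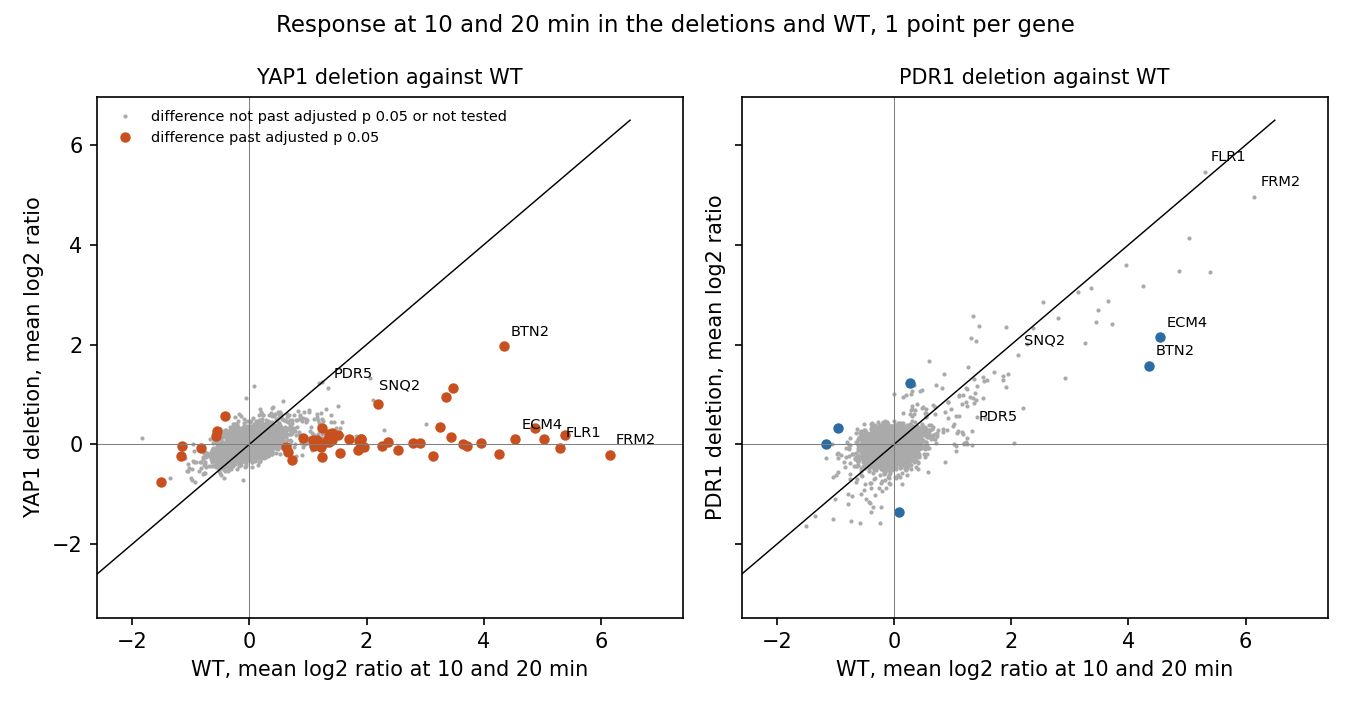
Mean log2 ratio at 10 and 20 min in the YAP1 deletion (left) and the PDR1 deletion (right) against WT, for genes with a value on all arrays drawn, with the line of equal response. FLR1 stood at 5.30 in WT and near 0 in the YAP1 deletion, and called genes that lack a value on 1 array are not drawn.

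Set side by side, the deletions differed most at FLR1. It was lower in the YAP1 deletion than in the PDR1 deletion by a log2 difference of -3.72 ± 0.67 (adjusted p = 0.0455), and YML131W (-2.84 ± 0.52), SDL1 (-2.70 ± 0.48), ATR1 (-2.22 ± 0.32) and OYE2 (-1.62 ± 0.24) were lower as well. ICT1 (1.07 ± 0.18), VHR1 (1.09 ± 0.18) and NOP56 (0.73 ± 0.12), a protein of ribosome assembly, were higher in the YAP1 deletion. Also higher were 4 Gag reading frames of Ty transposons, from 0.67 to 0.92, whose near-identical copies share hybridisation. SDL1, OYE2, YML131W, ICT1, VHR1, NOP56 and the Gag frames fall outside the rule for this contrast and were chosen after their values were seen. In limma 16 of 4324 genes passed, 11 higher and 5 lower (569 at an unadjusted p under 0.05, 216 by chance). Leaving out the 4 or 20 min arrays, the YAP1 deletion array at 4 or 20 min, the PDR1 deletion array at 4, 10 or 20 min, the WT array at 4 min or the 3 arrays that follow probe order ended every call. The count was 32 and 2 without the 2 or 10 min arrays, 34 and 4 without the YAP1 deletion array at 2 or 10 min, 4 without the WT array at 10 min and 1 without the PDR1 deletion array at 2 min. It was 0 without the time block or with the 30 s arrays included, 9 with only the arrays of these 2 strains, 8 with robust shrinkage and 9 with the probe trend removed.

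Whether a difference between strains depended on time was tested as late (10 and 20 min) minus early (2 and 4 min). For the YAP1 deletion minus WT the difference fell most for FRM2 (-5.36 ± 0.74), ECM4 (-4.07 ± 0.36) and YCR102C (-3.66 ± 0.54). For the PDR1 deletion minus WT it fell most for BTN2 (-3.18 ± 0.23), CUP1-1 (-2.94 ± 0.37) and HSP104 (-2.75 ± 0.33). In limma 16 of 4323 genes passed for the YAP1 deletion and 6 for the PDR1 deletion, all lower with time (216 and 397 at an unadjusted p under 0.05, where chance gives 216). BTN2 (-2.29), CUP1-1 (-2.46), TSL1 (-2.34), ECM4 and HSP104 (-1.97) passed for the YAP1 deletion too; the WT arrays are shared by both differences. Scaled arrays left 1 call in each, and leaving out 1 array changed both counts. For the YAP1 deletion it gave 5, 9, 33 and 10 without the WT array at 2, 4, 10 and 20 min and 4 and 6 without its own array at 2 or 20 min; for the PDR1 deletion it gave 1 without the 2 or 4 min array of either strain, 14 without the WT array at 10 min and 2 without the 20 min array of either strain.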

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

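Except for the correlations across junctions in the part on probe order, all tests named here, the bootstraps included, were chosen only after the result had been seen.

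Probes with neighbouring numbers shared their ratios most on 3 arrays, WT at 4 min (rank correlation of neighbours 0.391, next WT array 0.117) and the YAP1 deletion at 30 s (0.506) and at 4 min (0.408), and less on others, such as the YAP1 deletion (0.250) and the PDR1 deletion (0.240) at 2 min. The order of the probes on the array or in the plates fits: means of 8 probes on either side of a junction of chromosome arms, where numbers are adjacent but genes are not neighbours, correlated at 0.561 (0.498 to 0.594 over the 3 arrays; permutation p = 0.002 or less). Position on the chromosomes cannot be told apart: means across a centromere, where numbers are distant, correlated at 0.0686 (-0.194 to 0.136 over the 3 arrays; permutation p from 0.309 to 0.772), but a bootstrap over the few junctions ran from -0.522 to 0.527. A drug response of the cells gives no reason for ratios shared across junctions of chromosome arms, where genes are not neighbours. The correlation of 0.561 there (bootstrap over junctions 0.294 to 0.754) thus argues against it for these 3 arrays. The 30 s arrays alone cannot decide: the highest value, 0.506, stood at 30 s, but on 1 of the 3 arrays of that time.

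Yap1 targets rose in WT and not in the YAP1 deletion, whose mean at 10 and 20 min was 0.0327 of that in WT (bootstrap 0.00313 to 0.0725, 23 genes). Compression by a factor common to all genes of an array would lower both lists alike. Pdr1/Pdr3 targets reached 0.394 of WT at 10 and 20 min (0.206 to 0.807 over 14 genes) and 0.640 at 4 and 10 min (0.403 to 1.03, 15 genes). A common factor is thus unlikely as the whole cause. Compression that varies with spot intensity cannot be told apart, because the intensities were not used. At Yap1 targets the PDR1 deletion reached 0.791 of WT (0.669 to 0.907, 22 genes). This argues against an inflated WT time course, although the processing of that strain's arrays may differ. All these intervals run over genes and not over arrays. Less drug in the YAP1 deletion culture cannot be told apart, as there was 1 culture series per strain, so the loss is not assigned to the genotype. Of 14 Pdr1/Pdr3 targets only GRE2 (-4.55) and CIS1 (-2.91) passed as lower at these times. These 2 genes weigh heavily in the ratio of 0.394. SNQ2 (-1.22) and TPO4 (-0.54) were lower too but did not pass. PDR5 (-0.21), TPO1 (-0.21), YOR1 (-0.06) and ICT1 (0.03) differed less and did not pass either.

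General stress genes were higher in WT at 20 min than in the mean of both deletions, by 0.53 (0.21 to 0.94, 19 genes). A single aberrant WT array cannot be told apart, although the list mean at 40 min was 1.22 (0.84 to 1.60). A wider spread of that array cannot be told apart either; with scaled arrays 0.32 remained (0.11 to 0.58). These intervals run over genes and not over arrays, and each strain had 1 array at 20 min. A difference of the WT cultures other than the genotype cannot be told apart, because there was 1 WT series.

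In 126 series, each a measure over the arrays of a strain, 9 outliers were found, where chance gives 1 in 20 series. That share holds for exchangeable arrays, but these form time courses, and several outliers stood on the last array of a strain. They were the neighbour correlation of WT at 4 min above and 8 others. TUB1 stood at -0.35 in WT at 40 min (nearest WT array -0.08). The median of the phosphate regulon was -0.75 there (-0.12) and that of the ribosomal proteins -0.56 (-0.15). Genes 2-fold down numbered 32 in the YAP1 deletion at 20 min (2) and 40 in the PDR1 deletion at 20 min (5). In the YAP1 deletion PDR5 stood at 2.24 at 10 min (0.64), the median of amino acid synthesis at 0.18 at 20 min (0.05) and YAP1 at 0.29 at 4 min (0.04). The strain is deleted for YAP1, so the last value cannot be read as a change of its transcript. Its array also follows probe order.

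Each contrast was compared with other splits of its 8 arrays. Because time is a block, only the 8 splits with 1 array of each time on either side are comparable, which are too few for a share under 0.05. Among these the YAP1 deletion minus WT gave 6 genes (highest other 0) and the YAP1 minus the PDR1 deletion 16 (highest other 0). Late minus early gave 16 for the YAP1 deletion (highest other 47) and 6 for the PDR1 deletion (highest other 9). Over all splits, 2 of 35 reached the 6 genes, with 30 in the highest, 1 of 35 the 16 (highest other 4), and 3 of 34 and 6 of 34 the counts of late minus early. The split with 30 sets the WT arrays at 2, 10 and 20 min with the YAP1 deletion at 2 min against the others. It keeps WT against the YAP1 deletion at 10 and 20 min. This split therefore still holds the strain difference at those times, and its count need not point to other structure of the samples. The highest splits of late minus early set early WT beside late deletion arrays, which turns the contrast into the difference between strains. For the PDR1 deletion minus WT the real count was 0, which all 35 splits reach by construction (highest 1), so this test tells nothing about chance.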

How the results depend on the processing

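The values at 10 and 20 min, removal of the probe trend, the model without 3 arrays that follow probe order (WT and the YAP1 deletion at 4 min, the PDR1 deletion at 2 min), and arrays left out of late minus early were chosen only after the result had been seen; the other tests were planned. Counts of calls are given in the order WT, YAP1 deletion, PDR1 deletion, YAP1 deletion minus WT, PDR1 deletion minus WT, YAP1 minus PDR1 deletion (main 180, 5, 238, 6, 0, 16). With the own 30 s array subtracted they were 512, 1090, 863, 446, 388 and 1143. In that setting the same 30 s values enter all arrays of a strain. The 30 s array of the YAP1 deletion also had the highest rank correlation of neighbouring probes (0.506). For no setting was the cause of a changed count tested. Without a time block they were 48, 1, 130, 0, 0 and 0; with only the strains compared 0, 1, 4, 0, 0 and 9; at 10 and 20 min 392, 8, 160, 64, 12 and 49 (leaving out 1 array 80 to 459, 1 to 17, 57 to 201, 31 to 74, 2 to 50 and 5 to 77); without the 3 arrays that follow probe order 12, 0, 67, 0, 0 and 0; with an effect of at least 1 log2 33, 2, 29, 6, 0 and 7. With 30 s arrays included the YAP1 deletion had 12, its difference from WT 1 and from the PDR1 deletion 0. Robust shrinkage left 2 and 8 in these differences, and removal of the probe trend 9 in the latter. Scaled arrays gave 24 in the YAP1 deletion, 132 in the PDR1 deletion, 1 in the trend (main 5) and 1 and 1 in late minus early (main 16 and 6), where genes with all 12 values gave 3 for the PDR1 deletion. The trend had 11 calls with medians subtracted, 17 with all values and 662 on linear minutes. Leaving out 1 array or time gave 34 to 261 in WT, 0 to 6 and 36 to 240 in the deletions, 0 to 27, 0 to 0 and 0 to 34 in the differences, 0 to 59 in the trend and 4 to 33 and 1 to 14 in late minus early. The mean of the mating list in the YAP1 deletion minus WT reversed to -0.034 with 30 s subtracted. The correlation of both differences from WT was 0.408, and 0.129 and 0.252 with the WT arrays split by time. Elsewhere 1590 single-gene results stayed, 21 were stronger, 265 weaker and 0 reversed, where reversed is counted only for results that passed. The genes of the rule were picked as calls, for the WT response and the YAP1 deletion minus WT with 1 sign at all 4 times. Leaving out arrays could hardly turn their sign, so the 0 says little about stability. Of 868 values of genes that had not passed, 77 changed sign. For lists 268 results stayed, 9 were stronger and 52 weaker.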

Other observations

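The WT array at 40 min entered only the trend among the models, and no gene was tested on it alone. Sulphur genes stood there at a mean of 0.995, with 11 of 23 at least 2-fold up, among them MET16 (3.08) and MET17 (2.24), which make sulphite and homocysteine. General stress genes had 14 of 25 and heat shock genes 12 of 21 at least 2-fold up. In the other direction, 8 of 8 core histones (mean -1.25) and 21 of 57 ribosome biogenesis genes (mean -0.82) were at least 2-fold down. Because 1 array carries this, it may reflect that culture as well as the drug; the list mean of the general stress genes at 40 min was 1.22 (0.84 to 1.60 over genes).

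The counts shared at 10 and 20 min were chosen only after the result had been seen, and the tests of shared controls were planned. Both deletions were compared with the same WT arrays, which alone makes their differences correlate: r was 0.408 against 0.494 in 100 simulations of 4324 genes without a shared effect (0.454 to 0.537), while the covariance was 0.0214 against 0.00993. At 10 and 20 min 6 genes were lower than WT in both deletions, of 55 and 7, and 2 were higher in both, of 9 and 5. With the WT arrays split by time the correlation was 0.129 and 0.252, so part of the overlap could come from the shared WT arrays, although the covariance exceeded the simulated one by 0.0115. Of the probes, 352 genes had a value on all 11 arrays of WT and the YAP1 deletion and on none of the PDR1 deletion, so a part of the genome was unseen in that strain.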
